A study of Homo sapiens with 16 samples.

How the data were processed

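RNA was measured in 8 human cell lines, each with 1 DMSO and 1 AFN700 array after 20 hours, giving 16 arrays. Per the labels' protocols, cells were resuspended in fresh medium in 6-well dishes and treated, GRANTA-519 grew in DMEM and the other lines in RPMI with fetal bovine serum, total RNA was extracted with an RNeasy Plus kit, and biotin-labelled cDNA was made with a NuGEN Ovation amplification system. The culture medium of GRANTA-519 therefore differs from that of the other lines. The deposited values are linear probe set intensities made by the authors with MAS5, per the submitters' processing notes, with no version given in the sources used here. From the values, each deposited array has a mean intensity of 150 after 2% is trimmed from each end, a global scaling. No detection calls were used here, so a low intensity cannot be told from background.

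Probe sets were named through the platform table given, which lists 42898 probe sets, 41097 with 1 gene and 1801 with several. Another 11777 were not listed and stay unnamed here. Symbols were updated through Entrez numbers with the GRCh38.p14 RefSeq gene table, used for names only. Probe sets with several genes and the 62 control probe sets were left out. The probe set with the highest mean stood for each of 19775 genes. Of 14 reporter genes and 15 DMSO genes fixed before the data were examined, 12 and 12 had a probe set of their own, and the others are not reported here. Intensities were taken to log2(intensity + 3.3), the pseudocount being the 25th percentile of all values. Log2 differences are on that scale and understate changes of low genes. A gene was tested if it exceeded its array's 60th percentile on at least 2 arrays, which left 12260 genes. No further normalization was applied.

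Tests used limma 3.58.1 in R 4.3.3 with lmFit and eBayes with a trend. All 16 arrays entered 1 model with the cell line as a fixed block and an AFN700 term each for sensitive and insensitive lines (6 residual degrees of freedom), from which the 2 responses and their difference were taken. The response over 8 lines had 1 AFN700 term (7 degrees of freedom), and the DMSO comparison used the 8 DMSO arrays (6 degrees of freedom). The line pairs the arrays, since both come from the same cell line by the labels. Adjusted p-values are Benjamini-Hochberg over the genes tested, with 0.05 as the threshold. SE is the moderated standard error of a log2 difference. In the model of all 16 arrays it uses a spread shared by the 8 lines. The SE given for the sensitive lines is therefore not the spread of those 2 lines alone. Intensity means are given with the SD over lines. P-values of single genes measure the spread between lines, and between the single arrays that stand for them.

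In all, 28 gene lists with 508 entries, 437 of them measured, were written before the data were examined, from textbook knowledge. They include NF-kB, B-cell receptor, stress, cell cycle and metabolic lists and markers of T cells, myeloid cells, fibroblasts and epithelium. They were tested with limma's camera with a preset correlation of 0.01, the same test with an estimated correlation, and fry, each adjusted over the 28 lists. Camera compares a list with the other genes tested. With the preset correlation its p-value rests on the spread between genes. A small value there does not show that the shift repeats between lines. Fry and the exact tests below use the spread between lines. In each line a list's median was placed among 10000 random lists matched on mean expression in 20 bins. List means over lines were tested 2-sided and exactly, by sign flips (smallest p 0.0312 for 6 lines and 0.00781 for 8) and by the 28 splits of 8 lines into 2 and 6 (smallest p 0.0357).

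The rule for named genes took genes past the threshold with one sign in every line of the comparison, up to 12 per direction, or, where none passed, the 5 largest differences per direction among genes at an unadjusted p under 0.01. It added the fixed reporters and up to 4 genes of smallest p per list. Sex-linked markers and immunoglobulin and T-cell receptor segments were not named. Alternatives set before the data were examined were other pseudocounts, quantile normalization, centring, other filters, other rules for probe sets, no trend, no line block, a threshold of 0.10 and leaving out each line. Fits without JVM-13 and HBL-2 together, quantile normalization without JVM-13, the exact list tests over the lines without JVM-13 and camera on the DMSO arrays were added after seeing the data. The tests of scaling in JVM-13 and of the ribosomal protein genes were each redone after a first version had been seen, with rules that exclude an explanation less readily. The rule for exchanged arrays in JVM-13 was also raised after its value was seen, so that it supports an exchange less readily. The estimated correlation was part of the design. Figures were drawn with matplotlib 3.10.9.

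The steps were tested on simulated arrays with the real line means and fitted spreads of 12260 genes, 100 genes changed 2-fold and 100 changed 4-fold. The simulated noise had 1 spread per gene, equal in all lines. In the data the SD of the differences over genes ran from 0.35 in JVM-2 to 1.03 in JVM-13. The recovery and the false calls below hold for equal spreads and may differ in these lines. With changes in the sensitive lines only, the sensitive comparison recovered 17% of the 2-fold and 79% of the 4-fold genes with 5 false calls, and the difference recovered 13% and 66% with 5 false calls. With changes in all lines, the insensitive comparison recovered 77% and 99% with 7 false calls, and the comparison over 8 lines 90% and 100% with 9. With the spread fitted without JVM-13, the comparison over the 7 lines recovered 93% and 100% with 12 false calls. In the same simulations the noise was independent between genes. There a list lowered by 0.5 in the sensitive lines had a camera adjusted p of 0.000193, and 0 of 27 other lists were called. Without correlation between genes, the lack of false lists follows largely from the design and does not test camera's preset correlation. In the data, the correlation estimated for the sensitive comparison ran from -0.0956 for heat shock genes to 0.67 for cell cycle genes. For the NF-kB feedback list it was 0.20. False calls of lists at such correlations were not simulated.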

Results

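Gene expression was measured in 8 human B-cell lines that the labels group as mantle cell lymphoma lines. Each line was cultured for 20 hours with 5 uM AFN700, an inhibitor of the kinase IKKbeta, or with the solvent DMSO at 0.025%. IKKbeta phosphorylates the inhibitor of NF-kB and so releases the classical NF-kB transcription factors. One Affymetrix expression array was run per line and treatment, which gave 16 arrays. The labels call REC-1 and SP49 sensitive, and HBL-2, GRANTA-519, Z-138, Maver-1, JVM-2 and JVM-13 insensitive, to "stn" and ibrutinib. Ibrutinib inhibits BTK, a kinase of the B-cell receptor pathway. The treated array of JVM-13 is titled AFN700, while its treatment and description fields read AFN701, and it was kept as the treated array of its line. Every line had 1 array per treatment, so the line is the replicate and the values of a single line have no error of their own. The number of arrays limits the precision of every value.

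The first question was how far each line moved with the inhibitor. Over the 12260 genes tested, 433 genes in REC-1 and 458 in SP49 differed at least 2-fold between the AFN700 and the DMSO array. The counts were 323 in Z-138, 363 in Maver-1, 243 in JVM-2, 978 in GRANTA-519, 1737 in HBL-2 and 3986 in JVM-13. In GRANTA-519, 734 of the 978 were lower with AFN700, and in JVM-13, 3139 of the 3986 were higher. These counts describe pairs of arrays and carry no test. The DMSO array of JVM-13 stood apart, with a median log2 level of 7.27 against 7.83 to 8.03 on the other 15 arrays and a correlation across genes of 0.923 with its AFN700 partner against 0.964 to 0.990 in the other lines. In HBL-2 the actin 3'/5' ratio, a sign of RNA integrity, was 1.9 on the DMSO array and 16.7 on the AFN700 array. It went from 10.3 to 18.8 in Maver-1, from 2.73 to 6.39 in SP49, from 3.5 to 5.43 in Z-138 and from 2.01 to 3.43 in JVM-13. The ratio was a little lower with AFN700 in REC-1 (5.06 to 4.62), GRANTA-519 (2.78 to 2.72) and JVM-2 (2.12 to 2.09). The GAPDH 3'/5' ratio moved the same way in each line, from 1.2 to 3.2 in HBL-2, 3.96 to 4.52 in Maver-1 and 1.39 to 1.82 in Z-138. These ratios thus changed along with the treatment in several lines. Whether RNA integrity itself changed, and any effect on the responses, was not tested. The direction in JVM-13 held after quantile normalization (2959 higher and 784 lower, median difference 0.28) and turned with centring. With each array centred on its median, 1414 genes were at least 2-fold higher and 3057 lower, and the median difference over all genes went from 0.27 to -0.39. The same centring gave 739 higher and 888 lower in HBL-2, against 1194 and 543 as deposited, with a median difference of -0.04 against 0.16. In GRANTA-519 it gave 373 higher and 556 lower, against 244 and 734, with a median difference of 0.07 against -0.05. Quantile normalization gave 1299 higher and 503 lower in HBL-2, and 240 and 847 in GRANTA-519.

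**Figure D1:**
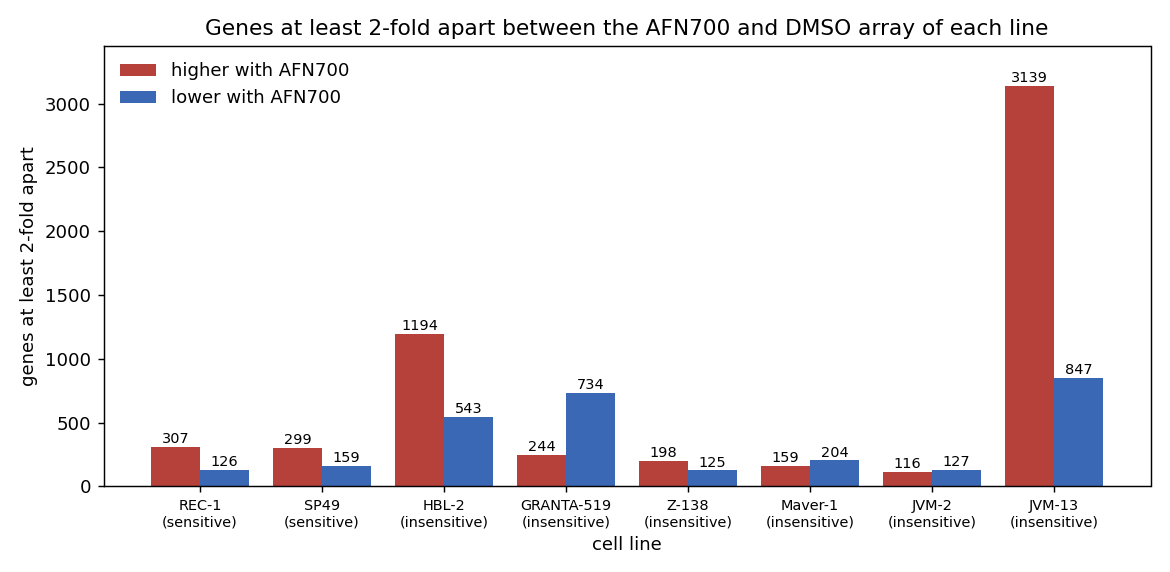
Bars give, for each cell line on the horizontal axis, the number of genes at least 2-fold higher (red) or lower (blue) on the AFN700 array than on the DMSO array, of 12260 genes tested. JVM-13 had 3139 higher and 847 lower, and JVM-2 had 116 higher and 127 lower.

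In the 2 sensitive lines, 5 of the genes that NF-kB induces had lower values with AFN700 in both lines, and none of them passed the threshold over all genes. CXCL10, a chemokine that attracts T cells, had a mean signal of 172 ± 105 (SD, n = 2 lines) with DMSO and 6.60 ± 5.09 with AFN700. Its log2 difference was -4.11 ± 1.02 (SE). In the insensitive line GRANTA-519 CXCL10 was at -4.52, and in the other insensitive lines between -1.67 and 0.99. TNFAIP3, which encodes the ubiquitin-editing enzyme A20 that restrains NF-kB, had a log2 difference of -2.11 ± 0.42. EBI3, a cytokine subunit, had -2.51 ± 0.72, the adhesion molecule ICAM1 had -1.78 ± 0.65, and NFKBIA, which encodes the inhibitor of NF-kB itself, had -1.47 ± 0.54.

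The 12 measured NF-kB reporter genes fixed in advance had log2 differences of one sign in both sensitive lines except for CCL4, a chemokine that was at 2.24 in REC-1 and -0.41 in SP49. RELB, an NF-kB subunit, was at -0.93 ± 0.48, the B-cell transcription factor IRF4 at -0.85 ± 0.39 and the anti-apoptotic gene BCL2A1 at -0.72 ± 0.31. IRF4 was at -0.30 in REC-1 and -1.39 in SP49. NFKBIE was at -0.60 ± 0.37, TRAF1 at -0.55 ± 1.03, the activation marker CD83 at -0.40 ± 0.32 and NFKB2 at -0.11 ± 0.48, while CCL4 had a mean of 0.92 ± 0.65. The other genes taken by the rule for large differences, none past the threshold, were SGPP2 (-1.72 ± 0.47) and PLXDC2 on the lower side. The signals of PLXDC2 in these lines, 11.1 and 8.1 with DMSO and 1.2 and 1.3 with AFN700, lie near the pseudocount of 3.3, so no size is given for it. On the higher side the genes were the ribosomal RNA precursor RNA45SN5 (1.83 ± 0.53) and LINC02482 (1.65 ± 0.38), which began at 12.4 in REC-1 and 6.2 in SP49, so its size depends in part on the pseudocount. ODAD1, DEPP1 and GGT7 were also taken and get no size, since ODAD1 began at 2.9 in REC-1, and DEPP1 at 4 and GGT7 at 1.6 in SP49. DEPP1 differed by 0.27 in REC-1, so its mean rested on SP49.

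**Figure D2:**
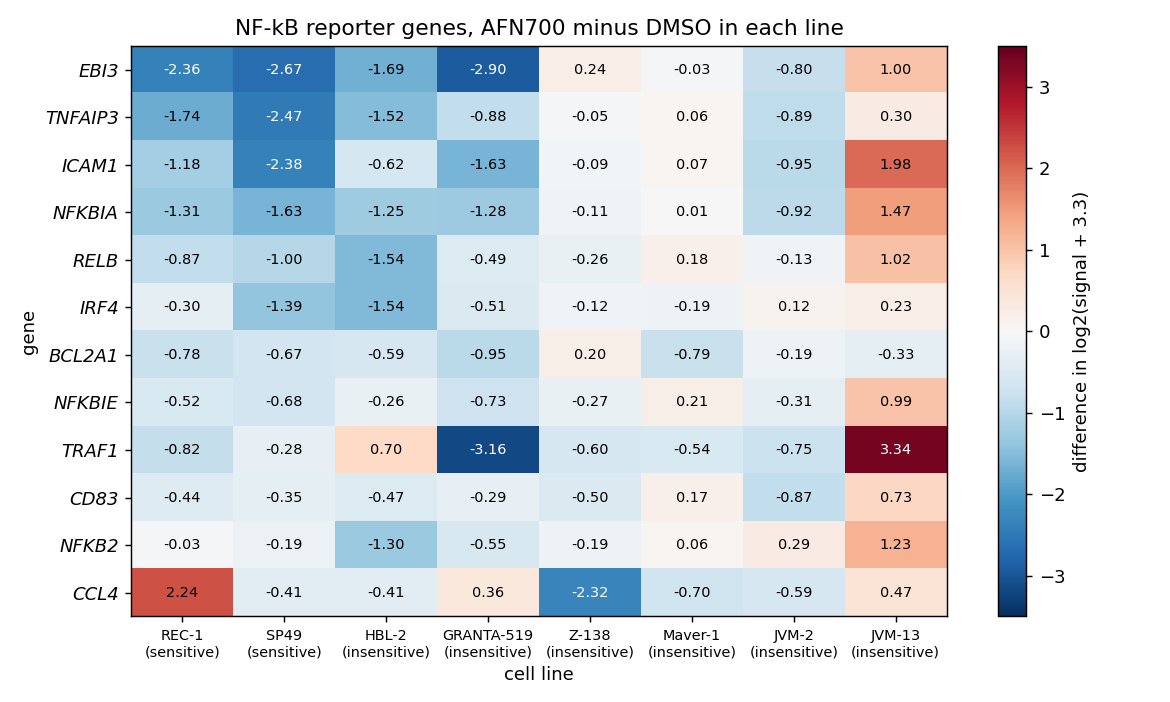
Each cell gives the difference in log2(signal + 3.3) between the AFN700 and the DMSO array of one line (columns) for one NF-kB reporter gene (rows), blue for lower and red for higher with AFN700. NFKBIA was at -1.31 in REC-1 and -1.63 in SP49, at 0.01 in Maver-1 and at 1.47 in JVM-13.

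Of the 18 measured NF-kB feedback and signalling genes, 15 had a negative log2 difference in the sensitive lines, and the list's mean was -0.46 in REC-1 and -0.58 in SP49. The list was lower by limma's camera test (adjusted p = 1.65e-06 with a preset correlation of 0.01), and the adjusted p was 0.293 with an estimated correlation. By fry, which uses the spread between lines, the adjusted p was 0.955. TNFAIP3 alone passed when adjusted over the list alone, and 3 genes did so without JVM-13. Of 24 NF-kB targets of survival and adhesion, 18 were negative (mean -0.57, adjusted p = 2.18e-08, and adjusted p = 0.293 with an estimated correlation). PLEK, which encodes the platelet protein pleckstrin (-1.41 ± 0.24), CFLAR, an inhibitor of caspase 8 (-1.45 ± 0.43), and EBI3 passed when adjusted over the list alone. Of 15 chemokines and cytokines of activated B cells, 11 were negative (mean -0.84, adjusted p = 1.21e-07, and adjusted p = 0.293 with an estimated correlation). CXCL10, CXCL9 (-2.50 ± 0.83), TNF (-1.24 ± 0.35) and lymphotoxin beta, LTB (-1.15 ± 0.39), passed when adjusted over the list alone.

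A further 2 lists passed the camera test in the sensitive lines, and none of their members passed when adjusted over the list alone. The MYC target and ribosome biogenesis list was lower (mean -0.18, 14 of 21 genes negative, adjusted p = 0.0124, and adjusted p = 0.293 with an estimated correlation). POLR1B, a subunit of RNA polymerase I, was at -0.60 ± 0.21 and WDR12 at -0.57 ± 0.25. The homing and egress receptor list was higher (mean 0.40, 12 of 17 genes positive, adjusted p = 0.0294, and adjusted p = 0.448 with an estimated correlation). Without JVM-13 in the fit its adjusted p was 0.0503. RGS1 was at 1.74 ± 0.72, the receptor gene S1PR4 at 1.27 ± 0.64, P2RY8 at 0.56 ± 0.22 and the chemokine receptor gene CXCR4 at 0.38 ± 0.13.

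Over all genes, limma called 0 of 12260 in the sensitive lines at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 360 genes, 278 of them higher and 82 lower, where chance alone gives 613. The count was 795 without JVM-13 and 1353 without JVM-13 and HBL-2, a pair left out after the data were seen. The lines in a fit share 1 spread, and the median SE went from 0.36 to 0.28 and 0.23. A count below 613 therefore does not show that the sensitive lines moved less than chance. An exact test over 2 lines cannot go below p = 0.5. Without JVM-13 and HBL-2 limma called 5 genes, and with only the sensitive lines in the fit it called 313.

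In the 6 insensitive lines the lists moved line by line. The mean of the NF-kB feedback list was -0.60 in GRANTA-519 and -0.43 in JVM-2, with 16 of 18 genes negative in each, -0.10 in Z-138, -0.08 in HBL-2, -0.004 in Maver-1 and 0.80 in JVM-13. The median over the genes had the opposite sign in HBL-2 (0.17) and in Maver-1 (0.06). Among 10000 random lists of matched expression, the list's median lay at percentile 0.32 in GRANTA-519, 0 in JVM-2, 8.45 in Z-138, 41.4 in HBL-2, 72.7 in Maver-1 and 96.5 in JVM-13. The corresponding percentiles were 0 in REC-1 and 0.02 in SP49. NFKBIA was at -1.24 in HBL-2, -1.28 in GRANTA-519 and -0.92 in JVM-2, at -0.11 in Z-138 and 0.01 in Maver-1, and at 1.47 in JVM-13. TNFAIP3 was at -1.52 in HBL-2, -0.87 in GRANTA-519, -0.89 in JVM-2, -0.05 in Z-138, 0.06 in Maver-1 and 0.30 in JVM-13. ICAM1 had the sign of NFKBIA in each of the 6 lines, and EBI3 did apart from 0.24 in Z-138 and -0.03 in Maver-1, where its DMSO signals were 1.1 and 1.7. The feedback list was at 0.13 in JVM-13 and -0.28 in HBL-2 with arrays centred, and in Maver-1 at 0.005 after quantile normalization. Centring gave -0.48 in GRANTA-519, -0.43 in JVM-2, -0.11 in Z-138 and -0.01 in Maver-1.

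Over the 6 lines the feedback list had a mean of -0.07 ± 0.48 (SD, n = 6 lines, exact 2-sided sign-flip p = 0.781). The camera test gave an adjusted p of 0.0599, and of 0.528 with an estimated correlation. Without JVM-13 the mean was -0.24 ± 0.26 (n = 5, exact sign-flip p = 0.0625, the smallest that 5 lines allow), with a camera adjusted p of 0.00185, and of 0.416 with an estimated correlation. Reporter means over the 6 lines were -0.70 ± 0.41 (SE) for EBI3, -0.53 ± 0.38 for CCL4, -0.50 ± 0.24 for TNFAIP3, -0.44 ± 0.18 for BCL2A1, -0.35 ± 0.31 for NFKBIA and -0.33 ± 0.22 for IRF4. ICAM1 was at -0.21 ± 0.38, CD83 at -0.20 ± 0.18, RELB at -0.20 ± 0.28, TRAF1 at -0.17 ± 0.60, NFKB2 at -0.08 ± 0.28 and NFKBIE at -0.06 ± 0.22. Without JVM-13 TRAF1 was at -0.87 ± 0.40, NFKBIA at -0.71 ± 0.20, ICAM1 at -0.64 ± 0.25, RELB at -0.45 ± 0.24, CD83 at -0.39 ± 0.13, NFKB2 at -0.34 ± 0.22 and NFKBIE at -0.27 ± 0.15.

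In all, 9 lists passed the camera test in the insensitive lines, all lower, and 0 did with an estimated correlation, where the smallest adjusted p was 0.131. The NRF2 target list, genes of the oxidative stress response, was negative for 11 of 11 genes (mean -0.21, adjusted p = 7.56e-06, and adjusted p = 0.131 with an estimated correlation). TXNRD1, thioredoxin reductase, was at -0.42 ± 0.12 and thioredoxin, TXN, at -0.24 ± 0.08. The chemokine and cytokine list had 12 of 15 genes negative (mean -0.40, adjusted p = 3.00e-05, and adjusted p = 0.322 with an estimated correlation). LTA, lymphotoxin alpha, was at -0.73 ± 0.29, and the chemokine CCL22 at -0.68 ± 0.35. The NF-kB survival and adhesion list (mean -0.12, 16 of 24 negative) had an adjusted p of 0.00132, and of 0.505 with an estimated correlation. The integrated stress response list (mean -0.14, 17 of 21 negative) had 0.00132 and 0.322 in the same order, with the serine synthesis gene PSAT1 at -0.41 ± 0.16. The early response genes of the B-cell receptor (mean -0.15, 12 of 16 negative, adjusted p = 0.00289, and 0.409 with an estimated correlation) held the activation marker CD69 at -0.49 ± 0.14.

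The other 4 lists were glycolysis and hypoxia (mean -0.06, adjusted p = 0.00949), MYC targets (-0.02, adjusted p = 0.0301), aryl hydrocarbon receptor targets (-0.16, adjusted p = 0.0413) and cell cycle (-0.03, adjusted p = 0.0415). With an estimated correlation their adjusted p-values were 0.322, 0.322, 0.322 and 0.709. The cell cycle mean was -0.88 in GRANTA-519, where 37 of 37 genes were lower, and 1.07 in JVM-13, whose DMSO array stood apart. With arrays centred that mean was -0.76 in GRANTA-519 and 0.405 in JVM-13, where 12 of 37 genes were lower. Without JVM-13, 14 lists passed the camera test, 13 lower and cholesterol synthesis higher (mean 0.15, adjusted p = 0.0109, and 0.416 with an estimated correlation), but the B-cell receptor early response genes (adjusted p = 0.139) and the aryl hydrocarbon receptor targets (adjusted p = 0.143) did not. With an estimated correlation 0 of the 28 passed, the smallest adjusted p being 0.254. Means without JVM-13 were -0.32 for NF-kB survival and adhesion genes, -0.25 for cell cycle, -0.13 for MYC targets and -0.07 for the early response genes. With all 6 lines no member of any of the 9 passed when adjusted over its list alone. Without JVM-13 CD80 (-1.30 ± 0.26) in the survival and adhesion list, CD69 (-0.45 ± 0.12) in the early response list and PSAT1 (-0.52 ± 0.14) in the integrated stress response list did.

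**Figure D3:**
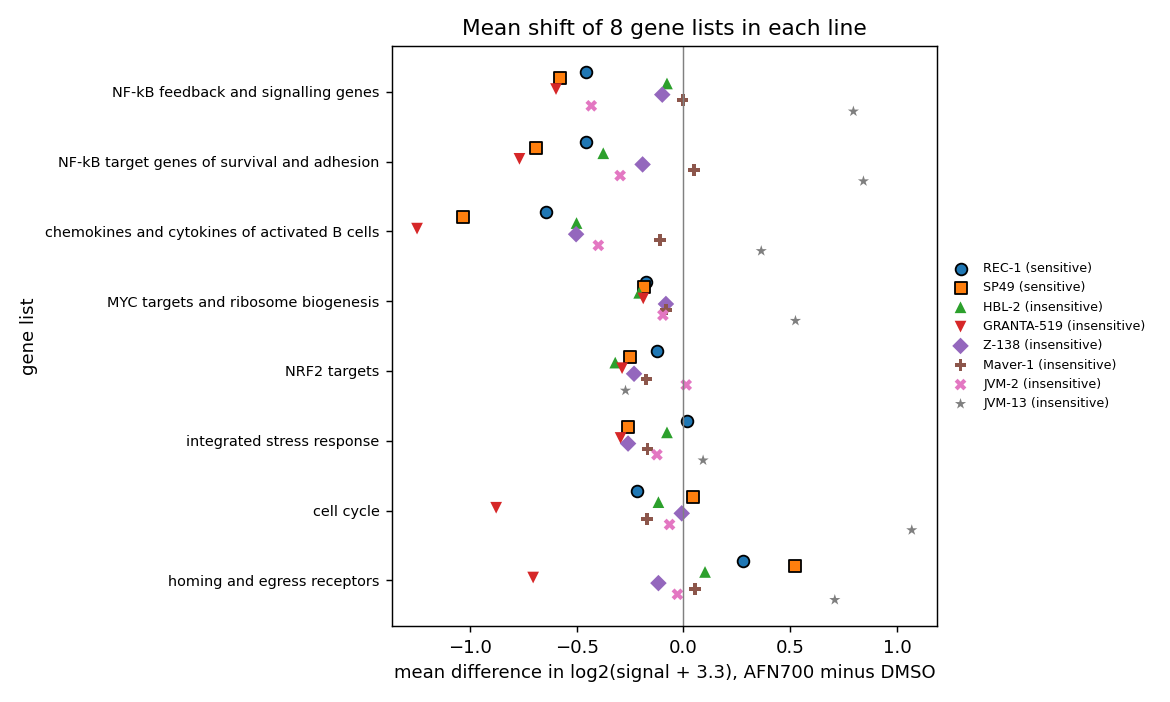
Each symbol gives one line's mean difference in log2(signal + 3.3) between AFN700 and DMSO over the genes of one of 8 lists, with the sensitive lines outlined in black. For the NF-kB feedback genes REC-1, SP49, GRANTA-519 and JVM-2 lie between -0.60 and -0.43, and JVM-13 lies at 0.80.

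Limma called 0 of 12260 genes over the insensitive lines at an adjusted p under 0.05, and the lowest adjusted p was 0.757. At an unadjusted p under 0.05 there were 738 genes, 565 higher and 173 lower, against 613 by chance. The largest differences of one sign in all 6 lines, none past the threshold, were the histone gene H2AC17 (-1.07 ± 0.26), the G protein-coupled receptor kinase gene GRK2 (-1.02 ± 0.27), CHRNA6 (-0.93 ± 0.26) and FMNL3 (-0.88 ± 0.26). The rule also took JPH1, whose mean signals in these lines, 5.28 with DMSO and 1.20 with AFN700, lie near the pseudocount of 3.3, so no size is given for it. On the higher side they were PLAC8L1 (1.13 ± 0.29), STK36 (1.11 ± 0.33), LMNTD2-AS1 (1.05 ± 0.30), PSMG3-AS1 (1.04 ± 0.27) and CDKL3 (0.94 ± 0.22). PLAC8L1 began at 0.5 in JVM-2, and LMNTD2-AS1 at 4.2 and PSMG3-AS1 at 4.6 in JVM-13, so these sizes depend in part on the pseudocount. STK36 was at 3.21 in JVM-13 and between 0.30 and 1.01 in the other insensitive lines. HBL-2 lay farthest from 0 for GRK2 (-2.54), CHRNA6 (-2.14), LMNTD2-AS1 (2.775) and PSMG3-AS1 (2.25). The actin 3'/5' ratio of HBL-2 was 1.9 with DMSO and 16.7 with AFN700, which limits these sizes.

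The sensitivity label poses the question whether the responses differ. The NF-kB feedback list was lower in the sensitive lines by a log2 difference of -0.45 relative to the insensitive lines (exact 2-sided p = 0.286 over the 28 splits of the 8 lines into 2 and 6). Without JVM-13 the difference was -0.27 (exact p = 0.286 over 21 splits). Camera passed 5 lists in the test of the difference, and their adjusted p was 0.663 for each with an estimated correlation. They were NF-kB feedback genes (adjusted p = 0.0092), NF-kB survival and adhesion genes (-0.45, adjusted p = 0.0092) and interferon response genes (-0.28, adjusted p = 0.0292) on the lower side. On the higher side they were homing and egress receptors (0.40, adjusted p = 0.0129) and chaperones of the unfolded protein response (0.14, adjusted p = 0.0292). The homing list was at 0.28 in REC-1 and 0.52 in SP49. Among insensitive lines it was at 0.71 in JVM-13, -0.70 in GRANTA-519 and between -0.12 and 0.10 in the rest. Without JVM-13 the differences were -0.26 for survival and adhesion genes, -0.17 for interferon response genes, 0.54 for homing receptors and 0.22 for chaperones, and the interferon list did not pass (adjusted p = 0.0716). In that fit MHC class II (0.32, adjusted p = 0.0043), cell cycle (0.16, adjusted p = 0.0368) and cholesterol synthesis (-0.20, adjusted p = 0.0104) passed as well, with 0.613, 0.755 and 0.613 at an estimated correlation. The cell cycle mean was -0.88 in GRANTA-519 and -0.17 to -0.01 in HBL-2, Z-138, Maver-1 and JVM-2, against -0.22 in REC-1 and 0.04 in SP49. The difference for cell cycle thus leaned on GRANTA-519. MHC class II was at -0.67 in GRANTA-519 and -0.27 in Z-138. It was at 0.125 in HBL-2, 0.12 in JVM-2 and 0.07 in Maver-1, against 0.30 in REC-1 and 0.08 in SP49. Without the term for the cell line 1 list passed. In the exact test over the 28 splits none of the 28 lists reached an adjusted p below 0.963. The smallest p of that test is 0.0357, so a list could pass after adjustment only if most lists reached it. The adjusted values therefore decide little. Unadjusted, no list went below the 0.286 of the NF-kB feedback list.

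Limma called 0 genes for the difference, and 185 had an unadjusted p under 0.05 where chance gives 613. That count was 344 without JVM-13 and 705 without JVM-13 and HBL-2. Genes with both sensitive lines on one side of all insensitive lines, none past the threshold, were TNFAIP3 (-1.61 ± 0.48), the cytokine IL7 (-1.59 ± 0.40), the receptor kinase EPHA2 (-1.53 ± 0.41) and ST3GAL2 (-1.29 ± 0.41). On the higher side they were GPER1 (1.42 ± 0.46) and TFAP2A-AS1 (1.29 ± 0.41). GPER1 was at 0.67 in REC-1, 2.05 in SP49 and 0.63 in the insensitive line HBL-2. The rule also took PLXDC2 on the lower side and ENDOU, NDRG4 and PRELID2 on the higher side. Their DMSO signals were at most 11.1 for PLXDC2 and 6.4 for ENDOU in the sensitive lines, and 2.9 for NDRG4 and 3.3 for PRELID2 in REC-1, so the pseudocount sets much of these folds and no size is given. TNFAIP3 was at -1.74 in REC-1 and -1.52 in HBL-2, an insensitive line. The difference for NFKBIA was -1.12 ± 0.62, for ICAM1 -1.57 ± 0.76, for EBI3 -1.82 ± 0.83 and for CCL4 1.45 ± 0.75. CCL4 was at 2.24 in REC-1 and -0.41 in SP49, and its difference ran from 0.12 to 2.77 over the settings tried. The remaining 7 measured reporters lay between -0.73 and -0.04. Without JVM-13 NFKBIA was at -0.76 ± 0.37 and CD83 at -0.01 ± 0.25, and 2 turned sign, TRAF1 from -0.39 to 0.32 and NFKB2 from -0.04 to 0.23.

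Over all 8 lines, PLEK was lower in every line (-0.65 ± 0.17) and passed when adjusted over its list alone, as did TXNRD1 (-0.37 ± 0.11) and TXN (-0.22 ± 0.07) in the NRF2 list. None of these passed over all genes. The NF-kB feedback list was lower in 7 of 8 lines (mean -0.18 ± 0.46 SD, exact sign-flip p = 0.320). Without JVM-13 it was lower in 7 of 7 (mean -0.32 ± 0.25 SD, exact p = 0.0156, the smallest that 7 lines allow, and 0.146 after adjustment over the 28 lists). That tally rests on Maver-1 at -0.004, and it was 6 of 7 after quantile normalization and 5 of 7 by the medians over genes. JVM-13, the line in which the list rose (0.80), was left out after its response was seen. The values without it therefore do not settle whether chance is excluded. The chemokine and cytokine list was also lower in 7 of 8 lines (mean -0.51 ± 0.50 SD, exact p = 0.0234, adjusted 0.250), with CXCL10 at -1.74 ± 0.62 and LTA at -0.79 ± 0.24. The NRF2 list was lower in 7 of 8 lines (mean -0.21 ± 0.11 SD, exact p = 0.0156, adjusted 0.250).

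Over the 8 lines 10 lists passed the camera test, all lower, and 0 did with an estimated correlation, where their adjusted p-values ran from 0.0675, that of the NRF2 list, to 0.851. Besides the 3 above, whose adjusted p-values were 0.00101 for NF-kB feedback, 8.65e-08 for chemokines and 2.74e-06 for NRF2, they were NF-kB survival and adhesion genes (2.74e-06), the integrated stress response (0.000236), MYC targets (0.00238), B-cell receptor early response genes (0.0102), cell cycle (0.0114), aryl hydrocarbon receptor targets (0.0114) and glycolysis and hypoxia (0.0164). Without JVM-13 the early response genes (0.224), the aryl hydrocarbon receptor targets (0.110) and glycolysis and hypoxia (0.127) did not pass, and plasma cell differentiation did (mean -0.15, adjusted p = 0.0416, and 0.510 with an estimated correlation). Fry, which tests whether a list moves one way, called 0 lists in each comparison with all lines, and MYC targets over the 7 lines without JVM-13 (adjusted p = 0.0175, mean -0.14, lower in 7 of 7). JVM-13 was singled out after its response was seen, and it was the only line in which this list rose (0.52). The call and the tally of 7 of 7 therefore lean on that choice. With all 8 lines the fry adjusted p of MYC targets was 0.665. Reporter means were -1.15 ± 0.41 (SE) for EBI3, -0.90 ± 0.28 for TNFAIP3, -0.63 ± 0.29 for NFKBIA, -0.60 ± 0.36 for ICAM1 and -0.51 ± 0.15 for BCL2A1. The other 7 lay between -0.46 (IRF4) and -0.09 (NFKB2). Without JVM-13 TRAF1 was at -0.78, NFKBIE at -0.36, NFKB2 at -0.27, ICAM1 at -0.97 and RELB at -0.59.

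Limma called 0 genes over all 8 lines, with a lowest adjusted p of 0.463 and 1005 genes at an unadjusted p under 0.05, of which 793 were higher. The largest differences of one sign in every line were CHRNA6 (-0.90 ± 0.21), LINC01619 (-0.69 ± 0.16), PLEK and AFMID (-0.58 ± 0.16) on the lower side, with JPH1 left without a size because most of its signals outside REC-1 are near the pseudocount. On the higher side they were LINC02482 (1.09 ± 0.20), LMNTD2-AS1 (1.002 ± 0.25), PSMG3-AS1 (0.98 ± 0.23) and PLAC8L1 (0.97 ± 0.25), with ODAD1 left without a size because it began at 2.9 in REC-1, 2.7 in JVM-2 and 0.7 in JVM-13. HBL-2, whose AFN700 array had a raised actin 3'/5' ratio, lay farthest from 0 for CHRNA6, LMNTD2-AS1 and PSMG3-AS1. Without JVM-13, 10 genes passed at an adjusted p under 0.05, each with one sign in 7 of 7 lines. CD80, a costimulatory molecule (-1.38 ± 0.21), DLEU2 (-1.03 ± 0.13), the proteasome subunit gene PSMD11 (-0.86 ± 0.14), CHML (-0.61 ± 0.10) and COX11 (-0.56 ± 0.09) fell. LINC02482 (1.20 ± 0.20), NSG1 (1.04 ± 0.16), ZBED5-AS1 (0.86 ± 0.14), CYP4V2 (0.78 ± 0.12) and BCR (0.72 ± 0.12) rose. These 10 were named after their values were seen.

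After 20 hours with DMSO alone, the arrays of the sensitive and insensitive lines differed in 1 gene at an adjusted p under 0.05. KCNJ16, a potassium channel subunit, had a signal of 1164 ± 974 (SD, n = 2 lines) in the sensitive lines and 4.07 ± 1.44 (n = 6 lines) in the insensitive lines, a log2 difference of 7.02 ± 0.64 (adjusted p = 0.0127). The insensitive level is near the pseudocount, so the size of the fold depends on it, and the adjusted p was 0.0503 without JVM-13 or Z-138, 0.0543 without HBL-2 and 0.169 without REC-1. Over the settings tried it ran from 0.00343 to 0.169. At an unadjusted p under 0.05 there were 702 genes, against 613 by chance. Of the 13 measured MHC class II presentation genes, 12 were lower in the sensitive lines (mean -2.53, camera adjusted p = 1.13e-05, and 0.327 with an estimated correlation), among them HLA-DRA at -4.40 ± 1.61 and HLA-DQA1 at -6.73 ± 1.88, whose mean signal of 3.85 in the sensitive lines makes the size depend on the pseudocount. No member of this list passed when adjusted over the list alone.

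Among the DMSO arrays, markers that passed when adjusted over their own list were lower in the sensitive lines for the plasma cell genes SDC1 (-5.26 ± 0.93), TNFRSF17 (-3.38 ± 0.83) and PRDM1 (-1.60 ± 0.49) and for the germinal centre gene GCSAM (-4.12 ± 0.64). They were higher for the chemokine receptor CXCR5 (5.06 ± 0.67), LTB (3.59 ± 0.63), the T-cell markers CD8A (4.17 ± 0.66) and CD3D (3.24 ± 0.86), and the B-cell factor PAX5 (1.27 ± 0.31). TXN (-0.95 ± 0.23), P2RY8 (-0.78 ± 0.21) and the BAFF receptor TNFRSF13C (2.02 ± 0.61) also passed in theirs. Without JVM-13 TNFRSF13C and TNFRSF17 did not pass in the alternative NF-kB list (adjusted p = 0.0617 for each), while TNFRSF17 did in the plasma cell list. Mean signals were 8.45 for GCSAM in the sensitive lines and 4.17 for CD8A and 1.85 for CD3D in the insensitive lines, so these folds depend on the pseudocount. The camera test on the DMSO arrays, chosen after the data were seen, passed 11 lists, 6 without JVM-13, and 0 with an estimated correlation in either case. With all lines their adjusted p-values ran from 0.327 to 0.764. Besides MHC class II, those lower in the sensitive lines were MHC class I (mean -0.87, adjusted p = 8.31e-05), plasma cell differentiation (-1.06, 0.000418), glycolysis and hypoxia (-0.34, 0.000435), NRF2 targets (-0.15, 0.0163), unfolded protein chaperones (-0.21, 0.0482) and aryl hydrocarbon receptor targets (-0.49, 0.0482). Those higher were T-cell markers (1.30, 0.00898), cell cycle (0.29, 0.0163), B-cell receptor signalling (0.40, 0.0179) and B-cell identity (1.21, 0.0338). Without JVM-13, whose DMSO array stood apart, the cell cycle mean was 0.13 and its adjusted p 0.092. B-cell identity (0.077), unfolded protein chaperones (0.077), NRF2 targets (0.070) and aryl hydrocarbon receptor targets (0.21) did not pass either. Fry for change in either direction called T-cell markers (adjusted p = 0.00163), germinal centre genes (0.00456) and homing and egress receptors (0.00554). Genes of the NF-kB and B-cell receptor pathways fixed in advance did not pass. CD79A was at 0.79 ± 0.28, CD79B at 1.34 ± 0.75, BTK at 1.08 ± 0.59, BIRC2 at 0.93 ± 0.40, TRAF3 at 0.84 ± 1.60, MAP3K14, the kinase of the alternative NF-kB pathway, at -0.72 ± 0.52, NFKB2 at -0.62 ± 0.60, RELB at 0.23 ± 0.61 and MS4A1 at 0.13 ± 0.19. The cell lines differed in the marks of mantle cell lymphoma. SOX11 had a DMSO signal of 0.1 in JVM-2 and 1.4 in JVM-13 and between 584 and 2336 in the other 6 lines, and cyclin D1, CCND1, had 78.7 and 4.8 against 394 to 2329. The log2 differences by label were 2.54 ± 2.60 for SOX11, 2.44 ± 1.90 for CCND1 and -3.37 ± 2.80 for CCND2. CCND1 was at -1.44 when all its probe sets were averaged, and at 1.36 without JVM-13.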

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

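Of the tests in this part, the scaling, the exchange of the JVM-13 arrays and the counts of other splits were chosen after the result was seen. In all, 47 sets of 6 insensitive lines were searched for a line far from the rest, and 5 gave one. Chance flags about 1 in 20 such sets, or 2.4 here. Of the 5, 4 are JVM-13.

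JVM-13 lay far above the other insensitive lines in the mean shift of MHC class I presentation genes (1.17, the next line 0.00) and of MYC targets and ribosome biogenesis (0.52, the next -0.08). It also did so in genes at least 2-fold higher with AFN700 (3139, the next 1194). The MHC class I mean of JVM-13 was 0.50 with arrays centred, where 7 of its 14 genes were lower, and 1.14 after quantile normalization. The median log2 level of its DMSO array was far below the rest (7.27, the next 7.83). The actin 3'/5' ratio of the Maver-1 DMSO array was far above the other insensitive DMSO arrays (10.3, the next 3.5).

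The response of JVM-13 ran against the mean of the other lines, and 3 technical explanations were weighed. Its correlation across genes with single lines ran from -0.303 with GRANTA-519 to 0.119 with HBL-2, with a median of -0.044. Scaling alone was not settled, since the shift of the NF-kB feedback list in JVM-13 was 0.74 after quantile normalization, the first version of the test and alone evidence against scaling, but 0.13 with arrays centred, added later. An aberrant DMSO array is a candidate explanation, because for 76.8% of the genes at least 2-fold apart in JVM-13 the DMSO value was the one farther from the other lines, against 41.4% to 56.4% in the other 7 lines. For exchanged arrays the test decides nothing, since the response of JVM-13 correlated across genes with the mean of the other lines at -0.146 and turning its sign must give 0.146, whose size was below the median of 0.219 in the other lines. With 1 array per treatment nothing here decides between these explanations, and a true opposite response or the compound name AFN701 in the labels stays open and untested.

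The response of 5 lists differed between sensitive and insensitive lines by the camera test of the difference with a preset correlation. The mean differences were -0.45 for NF-kB feedback genes, -0.45 for NF-kB survival and adhesion genes, -0.28 for interferon response genes, 0.14 for chaperones of the unfolded protein response and 0.40 for homing and egress receptors. None passed with an estimated correlation, and without JVM-13 the interferon list had an adjusted p of 0.0716. In the exact test over 28 splits their unadjusted p-values were 0.286 or higher, where the smallest possible is 0.0357. The differences without JVM-13 were, in the same order, -0.27, -0.26, -0.17, 0.22 and 0.54.

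Exchanging DMSO and AFN700 within lines tested whether chance can be excluded. For called genes the real count was 0, which every pattern reaches (32 of 32 in the insensitive lines, 100 of 100 drawn over 8 lines, highest other 0 in both), so that count decides nothing. For genes at an unadjusted p under 0.05, 10 of the 32 patterns gave as many as the real 738 (highest other 1393). Over 8 lines 7 of the 100 gave as many as the real 1005 (highest other 1459), so chance is not excluded there. Over the 7 lines without JVM-13, 1 of 64 patterns, the real one, gave as many as 10 called genes and the highest other was 0. JVM-13 was singled out after its response was seen to run against the mean of the other lines, so this count of agreement between the rest does not settle whether chance is excluded. For the difference of responses, 20 of 28 splits gave as many as 185 genes, so chance is not excluded. The highest other, 3699, grouped HBL-2 with JVM-13, and the 7 splits with JVM-13 in the pair gave at least 1204 against at most 630 in the rest, so the splits follow that line rather than the label.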

How the results depend on the processing

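Among the settings below, leaving out JVM-13 and HBL-2 together and quantile normalization without JVM-13 were chosen after seeing the data. The cause of a change was not tested unless stated. Counts of called genes for the insensitive lines and for the difference stayed at 0 in every setting run, including the fit with no replicate block, which also left 0 for the sensitive lines and for all 8 lines. The sensitive count was 313 with only the sensitive lines in the fit, where 1 residual degree of freedom remains, and 5 without JVM-13 and HBL-2 (TNFAIP3, PLEK, SGPP2, PSMD11 and RPS12). Over all lines it was 0 to 10 with 1 line left out, the 10 without JVM-13, and 34 without JVM-13 and HBL-2. The DMSO count of 1 was 3 with a pseudocount at the median, 2 with no filter, 2 without trend, 0 with a stricter filter, 0 with the mean of all probe sets, 0 to 47 with 1 line left out (47 without SP49, 0 without REC-1, HBL-2, Z-138 or JVM-13, 3 without GRANTA-519 and 2 without JVM-2), and 0 in both added settings. KCNJ16 kept its direction wherever it was tested; the stricter filter removed it. It lost its call in 7 settings, with the mean of all probe sets at 5.15 (adjusted p = 0.113, range over settings 0.00343 to 0.169). For single genes and lines, 1933 values stayed as they were within the spread and the threshold, 52 moved, 7 lost a call and 4 gained one. No called value turned in sign, but 16 of 98 named gene values without a call did in some setting, among them CCND1 under DMSO (2.44, and -1.44 with the mean of all probe sets), CCL4 in the sensitive lines (0.92, and -0.41 without REC-1) and TRAF1 in the difference (-0.39, up to 0.71 without JVM-13 and HBL-2).

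List counts from camera were 0 with an estimated correlation in each comparison. The sensitive count of 5 was 9 after quantile normalization with or without JVM-13 and 4 to 9 with 1 line left out (9 without REC-1). The insensitive count of 9 was 4 to 14 with 1 line left out (4 without GRANTA-519, 14 without JVM-13) and 14 with quantile normalization without JVM-13. The count for the difference, 5, was 8 with a stricter filter, 3 with the mean of all probe sets, 1 with no replicate block and 2 to 7 with 1 line left out (2 without SP49, 3 without HBL-2). Over all lines it was 8 to 11 with 1 line left out. The insensitive shift of the NF-kB feedback list, -0.07, turned to 0.048 when the medians over genes in each line were averaged, while the median over genes of the mean response, -0.08, kept the sign. It ranged from -0.241 to 0.037 with 1 line left out, above 0 without GRANTA-519 (0.037) or JVM-2 (0.004). The sensitive shift stayed between -0.58 and -0.46, and the difference between -0.55 and -0.27, with 1 line left out. The median count of genes at least 2-fold apart, 445.5, was 196 with a pseudocount at the median, 1093 with no filter, 245.5 with a stricter filter and 261.5 with the mean of all probe sets. These follow in part from the construction, since filters change the genes counted. With a lone sensitive line left, it is assumed to vary like the others. Low intensities limit the size of folds such as those of KCNJ16 and CXCL10.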

Other observations

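In this part, the correlation of the NF-kB level with its shift and the closely matched ribosomal protein lists were chosen after the result was seen, and the genes and patterns were picked from these data. In GRANTA-519 the cell cycle genes were lower in 37 of 37 cases (mean -0.88), the MHC class II genes in 13 of 13 (mean -0.67) and the MHC class I genes in 13 of 14 (mean -0.54). With arrays centred the means were -0.76, -0.56 and -0.42, and the median difference over all genes went from -0.05 to 0.07. These are single array pairs without a test, and GRANTA-519 grew in a different medium.

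The other lists gave these mean shifts over 8 lines, none past an adjusted exact p of 0.05. T-cell markers were at 0.21 ± 0.21 (SD), p53 targets at 0.17 ± 0.20, myeloid markers at 0.24 ± 0.39, interferon response at 0.12 ± 0.33, homing receptors at 0.10 ± 0.43, D cyclins and lymphoma markers at 0.08 ± 0.29, MHC class II at 0.07 ± 0.44, MHC class I at 0.07 ± 0.48, alternative NF-kB components at 0.06 ± 0.24, germinal centre genes at 0.05 ± 0.27, the BCL2 family at 0.04 ± 0.17, cholesterol synthesis at 0.03 ± 0.23, plasma cell genes at 0.02 ± 0.54, B-cell identity at 0.01 ± 0.23, B-cell receptor signalling at -0.003 ± 0.24, unfolded protein chaperones at -0.02 ± 0.20, fibroblast and epithelial markers at -0.03 ± 0.20 and heat shock genes at -0.06 ± 0.08. Without JVM-13 the sign turned for plasma cell genes (-0.15), MHC class I (-0.09), B-cell identity (-0.06), MHC class II (-0.04) and D cyclins (-0.009). Interferon response was then at 0.03, homing receptors at 0.02, germinal centre genes at 0.01, alternative NF-kB components at 0.008, cholesterol synthesis at 0.09, B-cell receptor signalling at -0.07, unfolded protein chaperones at -0.07, fibroblast and epithelial markers at -0.05 and heat shock genes at -0.04.

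In Z-138 and Maver-1 the NF-kB feedback list barely moved, and a low starting level was tested first: the list's mean DMSO level in these lines was on average 0.289 above the lowest other line, HBL-2 at 6.85, which met the bound set in advance against it. After the value was seen the explanation was left open for the list as a whole, because the margin was 0.053 in Z-138 (0.525 in Maver-1) with single arrays, and because the list in HBL-2 itself shifted by -0.08 as deposited, although by -0.28 with arrays centred. Single genes were mixed. TNFAIP3 had a DMSO signal of 49.6 in HBL-2, 865 in Z-138 and 383 in Maver-1 with differences of -1.52, -0.05 and 0.06. NFKBIA had 229, 510 and 380 with -1.24, -0.11 and 0.01. A low start does not explain these 2 genes, which do not decide for the list. EBI3, of the survival and adhesion list, began near the floor, at 1.1 in Z-138 and 1.7 in Maver-1. The actin 3'/5' ratio of HBL-2, the line compared with, was 1.9 with DMSO and 16.7 with AFN700, which limits its differences. Over 8 lines the list's level and its shift had Pearson r = -0.109 (permutation p = 0.828) and Spearman rho = -0.381 (p = 0.36), and r = -0.004 without HBL-2 and Z-138, while over 7 lines without JVM-13 r was -0.799 (permutation p = 0.0456, 0.182 adjusted over 4 relations), rho was -0.679 (p = 0.11), and r was -0.643 without HBL-2 and Z-138, so a larger fall where the list starts higher is a hypothesis that rests on leaving JVM-13 out. A higher level of MAP3K14, the kinase of the alternative pathway, was not supported or excluded, with r = 0.183 (permutation p = 0.656, adjusted 0.828), rho = 0.262 (p = 0.536) and r = 0.308 without JVM-2 and REC-1, and over 7 lines without JVM-13 r = 0.177 (permutation p = 0.683, adjusted 0.828), rho = 0.071 (p = 0.906) and r = -0.081 without JVM-2 and Maver-1.

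Ribosomal protein genes were higher in the sensitive lines, by a mean of 0.42 in REC-1 (55 of 57 genes) and 0.14 in SP49 (51 of 57). The difference from the insensitive lines was 0.30 (exact p = 0.107 over 28 splits), and 3 of the 6 insensitive lines reached similar percentiles among closely matched lists, Z-138 (mean 0.15) and Maver-1 (0.04) 100 and GRANTA-519 (-0.01) 99.98, so a response tied to the label cannot be told apart from the spread between lines. Lists drawn from the 50 genes nearest in level to each had medians of 0.30 in REC-1 and 0.12 in SP49, and the ribosomal medians, 0.45 and 0.16, lay at or above percentile 99.99 of those lists. A first version with coarser matching in 20 bins gave percentile 100 in both lines and would have argued against a shift of all highly expressed genes. Quantile normalization left means of 0.08 and 0.04. It gives every array the same values at each rank, and these genes lie near the top (median rank 52). It therefore shrinks their shifts whatever the cause, as in JVM-13 (-0.30 to -0.004), and decides nothing here. By the matched lists' own medians, a shift of all highly expressed genes may account for much of the pattern and not clearly for all of it.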
